A study of Mus musculus with 6 samples.

How the data were processed

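The data were H3K9ac chromatin immunoprecipitation libraries of intestinal epithelial cells from the distal intestine of germ-free, E. coli-monoassociated and conventionally housed C57BL/6 mice, 2 libraries per group and 6 in all. Groups and replicate numbers were taken from the sample labels. Per the labels, libraries were made with the ThruPLEX kit and read as single-end 50 bp reads on an Illumina HiSeq, with 20 M reads each. Per the submitters' processing notes, Bowtie 1.2.0, MACS2 2.1.1.20160309 and the mm10 build were used. Whether an input control was used, and the peak calling options, are not given in the sources used here.

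Each deposited file was 1 library's MACS2 peak list, so peaks were called per sample. The deposited lists gave, for each interval, the pileup at the summit (coverage by extended reads), the -log10 p-value, the fold enrichment as a ratio of pileup to background, and the -log10 q-value, together with the region class and the nearest RefSeq gene that the authors assigned. The deposited list of germ-free replicate 2 had 14 header names over 13 cells per line, with the values moved against the header, and held no summit and no pileup. Its columns were identified from the values: length equalled the distance from start to end, and fold and -log10 p were related as in the other 5 lists. Lines that repeated an interval for a further summit were merged, which left 4430, 17094, 1988, 870, 3117 and 15352 intervals from 4989, 17094, 2359, 1099, 3547 and 18032 lines (germ-free, E. coli and conventional, replicates 1 and 2 in that order).

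In the 5 lists with a pileup, the fold equalled the pileup plus 1 over 1 constant background plus 1, and the -log10 p equalled the Poisson tail with that background. In the list of germ-free replicate 2, which held no pileup, the background was inferred from the steps between fold values under the same formula, and the -log10 p followed the Poisson tail for the pileups so inferred. The backgrounds were 0.733, 0.579, 0.690, 0.403, 0.413 and 0.381 extended reads per base. The shortest interval was 146 or 147 bp in each list, so the extension length was alike and the background served as a measure of relative depth (100, 79.0, 94.1, 55.0, 56.4 and 52.0% of germ-free replicate 1). Read counts per library were not used here. The lowest fold was 4.04 and 3.80 in the germ-free, 4.14 and 4.28 in the E. coli and 4.25 and 3.62 in the conventional lists, so weaker enrichment is not in the lists, and a promoter without a peak may still carry the mark. Because no coverage tracks were used here, the values compared between libraries are calls, never scores.

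A gene had a promoter peak where an interval that the authors tied to it overlapped 1 kb on either side of its transcription start site; this differed from the authors' own promoter class at 3 or fewer intervals of any list. Gene names were matched to the RefSeq gene table of GRCm38.p6, the assembly behind mm10: of 10621 names 10567 matched, 54 did not, and 6 genes listed under several names were merged. Of these the protein-coding genes were kept (21900 in the table, 8097 with a promoter peak in any library), and 1730 of them had only promoter peaks shared with another gene. Regions were the 23987 merged intervals of all 6 lists, of which 378 were called in all 6 libraries and 15736 in 1, mitochondrial regions included. Overlaps and Jaccard indices were computed with bedtools 2.31.1, and everything else with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Mitochondrial intervals were left out of promoter shares and gene counts, and stayed in list lengths, overlaps and region counts: 2 such regions were called in all 6 libraries and 2 in both conventional libraries alone.

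For each ordered pair of groups, genes and regions called in both libraries of the first and neither of the second were counted. Peak numbers (log2), promoter shares and overlaps were compared by exact permutation of the libraries, 15 splits for 3 groups and 3 for 2 groups, two-sided except for the overlaps. The 22 gene lists were fixed before the files were seen. A list was tested for more or fewer losses than other genes of equal rank, by an exact two-sided test stratified over 5 quintiles of peak rank, with Benjamini-Hochberg adjustment over 96 tests and a threshold of 0.05. This list test was tried on the real germ-free peak ranks, with losses simulated per quintile and calls at an unadjusted p under 0.05. Of 400 random 12-gene lists 2.5% were called with no effect. Of 400 12-gene lists from the 2 highest quintiles, 91.5% were called with a planted loss. Of lists of strong peaks with no effect 2.0% were called with strata and 84.2% without. These rates do not describe the test after adjustment. List enrichment among marked genes used Fisher's exact test, a test added after the data were seen.

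Named genes followed a rule fixed beforehand: per ordered pair of groups, the 10 genes of the both-and-neither pattern with the highest smaller percentile rank of peak significance in the first group, up to 4 such members per list, all such members of the antimicrobial, histone acetylation, interferon and circadian lists, and up to 4 members per list with a peak in all 6 libraries. Some genes that the rule selects are not reported here. Genes named outside this rule were chosen after their values were seen.

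Alternatives were a -log10 q of 5 or more, the 870 most significant intervals of every list, a 2.5 kb window, an overlap of 500 bp, 0.5 or more of a region covered by the peaks of a library, autosomes only, a replicate block, the list test without strata, and each library left out in turn. Added after the data were seen were a fold of 5 or more, the longest list of the germ-free and of the conventional group alone, pairwise promoter shares under these settings, promoter shares without regions called in all 6 libraries, and the list test with shared promoters counted once.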

Results

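Acetylation of lysine 9 of histone H3 (H3K9ac), a mark of active promoters that acetyltransferases place and histone deacetylases remove, was profiled by chromatin immunoprecipitation and sequencing. The chromatin came from intestinal epithelial cells of the distal intestine of C57BL/6 mice. The mice were germ-free, monoassociated with Escherichia coli (colonized with that bacterium alone) or conventionally housed with a normal microbiota, and each of the 3 groups had 2 libraries. Each library had its own list of called peaks on mm10. The lists held 4430 and 17094 intervals in the germ-free libraries (replicates 1 and 2), 1988 and 870 in the E. coli-monoassociated libraries, and 3117 and 15352 in the conventional libraries. The intervals covered 1208 and 6622 kb, 574 and 306 kb, and 989 and 5926 kb in the same order. The labels stated 20 M reads per library. The background pileup behind each list, which scales with the reads used, was 0.733 and 0.579 (inferred from fold values) in the germ-free, 0.690 and 0.403 in the E. coli and 0.413 and 0.381 in the conventional libraries. Nothing in the labels says that the libraries came from separate animals, so the spread between replicates may be technical.

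Promoters of the intestinal epithelium carried the mark in every library. A promoter peak, within 1 kb of a transcription start site, was called for 8097 protein-coding genes in at least 1 library and for 218 genes in all 6. The 218 included Cdx2, a homeobox factor that specifies intestinal identity, and Vil1, which encodes the microvillus protein villin. At Vil1 (chromosome 1, start site at 74409384) the strongest promoter peak had an enrichment of 10.4-fold and 13.9-fold in the germ-free lists, 10.1-fold and 9.98-fold in the E. coli lists, and 10.6-fold and 15.9-fold in the conventional lists. At Cdx2 (chromosome 5, start site at 147307249) these values were 13.3-fold and 14.6-fold, 14.8-fold and 9.98-fold, and 14.2-fold and 22.4-fold. They are the authors' per-peak values, each relative to its own list, and serve only to describe and rank peaks within a list.

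Of 35 intestinal transcription factors, 9 had a promoter peak in all 6 libraries, among them Klf5, Klf4 and Gata5. Of 37 junction and barrier genes, 7 did, among them the adhesion molecule Epcam, the claudin Cldn7 and the desmosomal cadherin Dsg2. Absorptive enterocyte genes with a peak in all 6 included the peptidase Anpep, the sodium pump subunit Atp1b1 and the amino acid transporter Slc6a19, whose promoter is shared with a neighbouring transcript. The acetyltransferase Ep300, the acetyl-lysine reader Brd2, the clock repressor Nr1d1, Nfkb1, the interferon gamma receptor Ifngr1 and the triglyceride enzyme Dgat1 also had a peak in all 6. So did the housekeeping genes Actb, Actg1 (promoter shared with 0610009L18Rik) and Hspa8, the ATP synthase gene Atp5b and the translation factor Eif4a2 (promoter shared with Snord2).

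Cell types outside the epithelium were nearly without calls. No gene of a 36-gene list for stroma, endothelium, muscle and nerve had a promoter peak in any library, and of 37 lymphocyte and myeloid genes 1 had a peak, in conventional replicate 2. Enteroendocrine genes had 1 call, in the same library, and Paneth cell genes had 2 calls, both in germ-free replicate 2. Goblet cell genes had calls for up to 9 of 21 (germ-free replicate 2) and stem cell and Wnt genes for up to 11 of 26 (conventional replicate 2). Against all 21900 protein-coding genes, intestinal transcription factors and junction genes were enriched among promoter-marked genes in each of the 6 libraries. The highest adjusted p was 4.1e-07 for the transcription factors and 1.9e-08 for the junction genes (Fisher's exact test, two-sided, Benjamini-Hochberg over 132 tests, a test chosen after the data were seen). Housekeeping genes were enriched in all 6 as well (highest adjusted p 0.00197 by the same exact test). Mitochondrial respiration and ribosomal genes were enriched in every library except E. coli replicate 2. By that exact test the ribosomal list passed narrowly in E. coli replicate 1 (5 of 38, adjusted p = 0.0487) and conventional replicate 1 (8 of 38, adjusted p = 0.0462). Mitochondrial respiration was the strongest list in germ-free replicate 1 (27 of 38, adjusted p = 5.3e-16 by the same exact test). In E. coli replicate 2, the shortest list, 14 of 35 transcription factors and 13 of 37 junction genes had a peak, against 1 of 38 ribosomal and translation genes and 2 of 38 mitochondrial respiration genes.

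**Figure D1:**
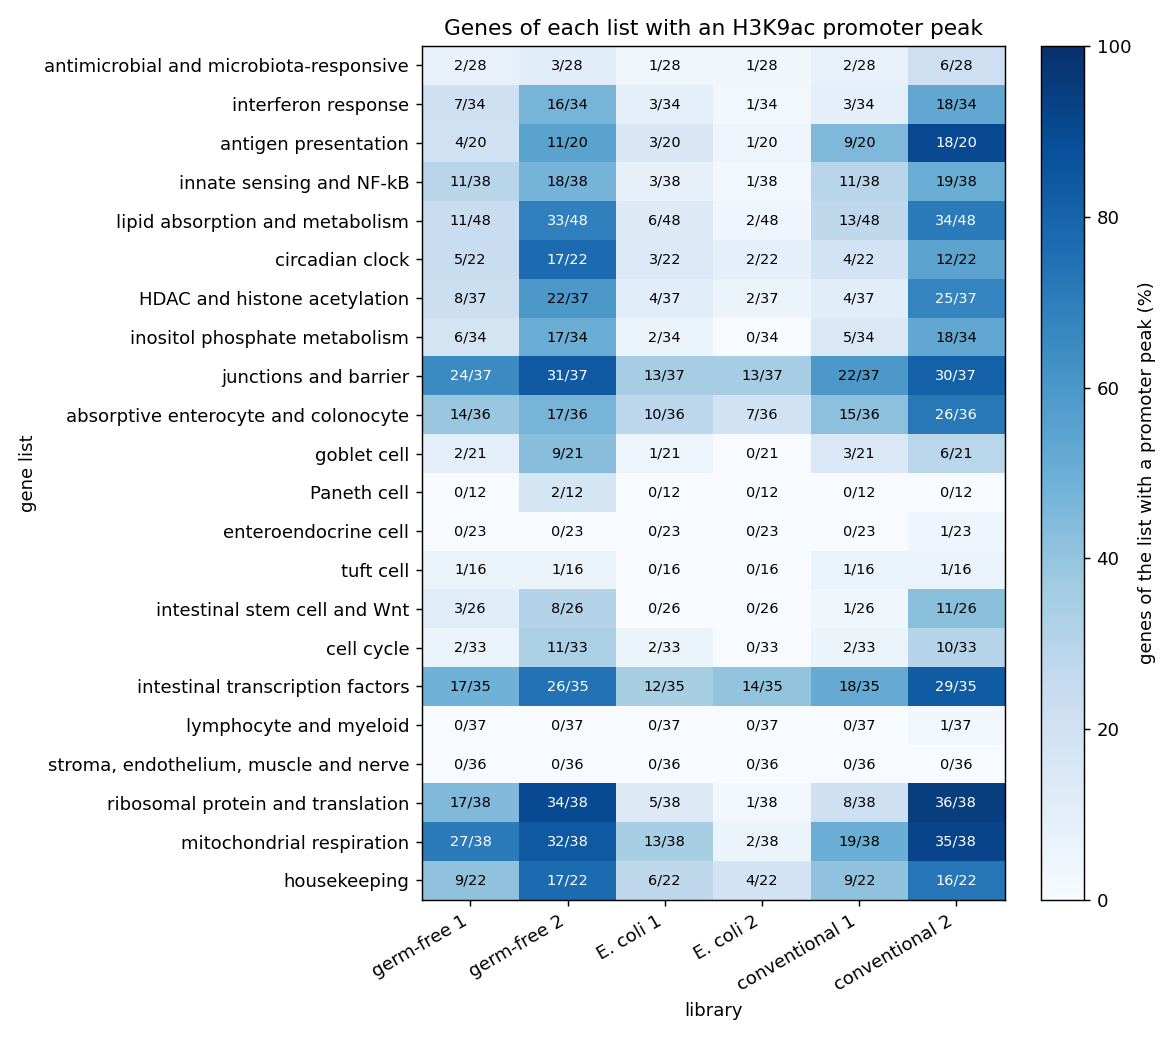
Genes of each of 22 gene lists with an H3K9ac promoter peak in each library, as a count over the protein-coding genes of the list and as a percentage (colour scale). Junction genes ran from 13 to 31 of 37 and stromal genes stayed at 0 of 36 in all 6 libraries, while the ribosomal list ran from 1 to 36 of 38.

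The E. coli-monoassociated libraries had the fewest called peaks, and their 2 lists lay below all 4 lists of the other groups. The group means were 10762 ± 8955 intervals in germ-free, 1429 ± 791 in E. coli-monoassociated and 9234.5 ± 8651 in conventional libraries (SD, n = 2 each). The shortest germ-free list was 2.23 times as long as the longest E. coli list, and the geometric means differed by 6.62 times. Replicates of one group differed by 3.86 times in germ-free, 2.29 times in E. coli-monoassociated and 4.93 times in conventional libraries. On the log2 scale the E. coli minus germ-free difference was -2.73 (exact permutation p = 0.333, two-sided) and the conventional minus germ-free difference was -0.33 (exact permutation p = 0.667). The groups held 62.8% of the sum of squares of log2 peak number (exact permutation p = 0.267 over 15 splits of the 6 libraries). With 2 libraries per group the smallest p is 0.333 for a pair of groups and 0.0667 for all 3, so no difference between groups could pass 0.05 by this test. Leaving out germ-free replicate 2 or conventional replicate 1 turned the conventional minus germ-free difference to 0.64 and 0.82, and the E. coli minus germ-free difference moved between -1.75 and -3.70 when single libraries were left out.

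**Figure D2:**
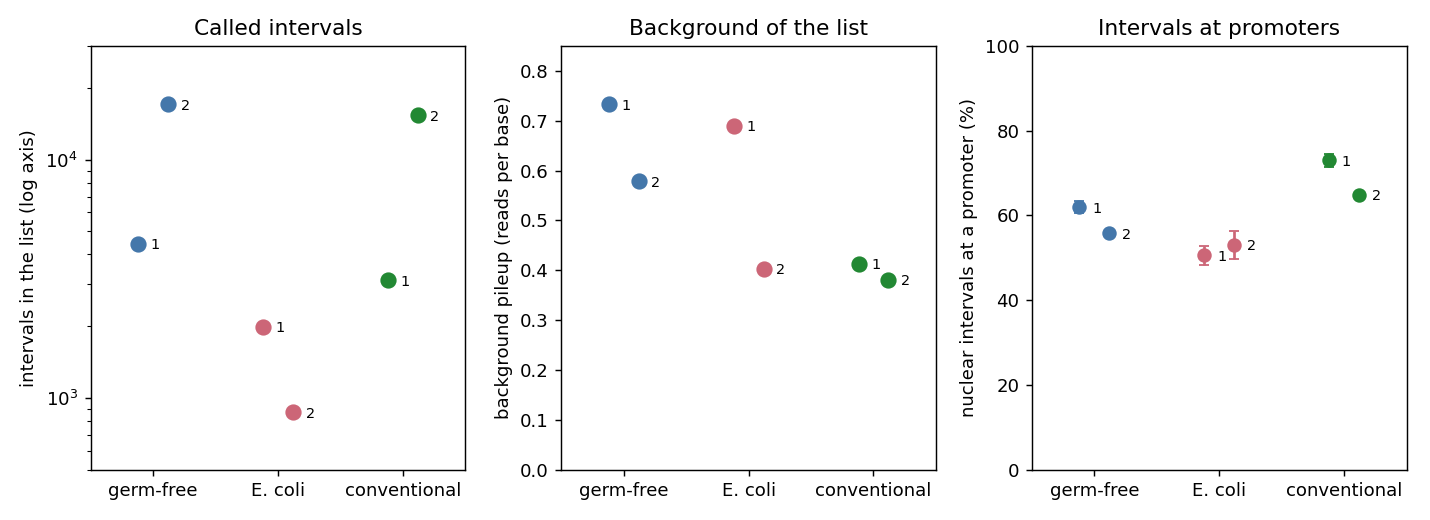
Called intervals per list on a log axis (left), background pileup of the list (middle) and percentage of nuclear intervals at a promoter with 95% Wilson intervals (right); each point is 1 library, numbered by replicate. Both E. coli lists (1988 and 870 intervals) lie below the other 4, while conventional replicate 2, with the lowest background pileup (0.381), has 15352.

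With all intervals counted, the share at promoters was highest in the conventional and lowest in the E. coli lists. The E. coli minus germ-free difference changed sign only when the non-promoter regions that all 6 lists share were dropped. Of the nuclear intervals, 61.9% (95% Wilson interval 60.5 to 63.3) and 55.8% (55.0 to 56.5) lay at promoters in the germ-free libraries. The shares were 50.6% (48.4 to 52.7) and 53.1% (49.8 to 56.4) in the E. coli libraries and 73.0% (71.4 to 74.5) and 64.8% (64.1 to 65.6) in the conventional libraries. These intervals cover counting error only. With all nuclear intervals the groups held 84.0% of the sum of squares (exact permutation p = 0.0667, the smallest that 15 splits allow). The non-promoter regions called in all 6 libraries weigh most on the shortest lists. Without them E. coli replicate 2 stood at 66.6%, above both germ-free libraries (64.2% and 56.4%) and conventional replicate 2 (65.6%), the E. coli minus germ-free difference turned from -6.94 to 0.672 percentage points, and the groups held 48.9% (exact permutation p = 0.467). Without all regions called in all 6 libraries, promoters included, the difference was -5.85 and the groups held 71.7% (exact permutation p = 0.133). Dropping non-promoter regions alone raises the share of short lists by construction. In the other direction, the difference was -30.8 at a -log10 q of 5 or more, -16.8 with the 870 most significant intervals of each list and -12.9 at a fold of 5 or more, with the common regions kept. Intergenic intervals made up 18.8% and 15.4% of the E. coli lists, 12.4% and 9.65% of the germ-free lists and 6.68% and 8.03% of the conventional lists. With only the 870 most significant intervals of each list, the groups held 74.7% (exact permutation p = 0.133).

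Libraries of one group were not the most alike in called sequence, by an index that unequal list lengths hold down. The Jaccard index in base pairs was highest between germ-free replicate 2 and conventional replicate 2 (0.324, 3069 kb shared), which share no group, and was 0.295 between the E. coli libraries, 0.144 between the conventional and 0.123 between the germ-free libraries. The 3 pairs within a group exceeded the 12 pairs between groups by 0.0290 on average (exact permutation p = 0.267, one-sided). The same pair of long lists shared 5652 promoter-marked genes, 87.1% of those of germ-free replicate 2. Of the genes marked in germ-free replicate 1, 92.4% were marked in germ-free replicate 2 and 95.5% in conventional replicate 2.

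Monoassociation with E. coli was set against the germ-free state, which asks what a single bacterial species does to H3K9 acetylation in the epithelium. Of 2226 genes with a promoter peak in both germ-free libraries, 1461 had none in either E. coli library (65.6%, 95% Wilson interval 63.6 to 67.6) and 230 had one in both. The strongest of the 1461 by rank was Ccnl1, a cyclin linked to splicing (chromosome 3, start site at 65958225), with peaks of 13.3-fold and 12.7-fold in the germ-free lists and peaks in both conventional lists. It was followed by the chaperone partner Chordc1, the MAP kinase phosphatase Dusp16, the adaptor protein gene Ywhah, the splicing genes Dhx38 and Txnl4b (1 shared promoter), the kinase Akt2, the actin capping subunit Capza2, the chloride transporter Clcn4-2 and the RNA-binding protein gene Hnrnpa3, whose promoter is shared with Gm6793. All 10 had a peak in both conventional libraries. In the other direction, none of the 248 genes with a peak in both E. coli libraries lacked one in both germ-free libraries (upper 95% Wilson limit 1.53%), and 22 did without E. coli replicate 2.

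Genes of histone acetylation and of the interferon response were among those marked in germ-free but not E. coli libraries, in numbers close to those of other genes of equal rank. Of 7 histone acetylation genes with peaks in both germ-free libraries, 4 had none after monoassociation, among them the corepressor subunits Sin3b and Rcor1 and the deacetylase Hdac2 (3.99 expected at equal rank, exact p = 1). Of 7 interferon genes, 5 had none, among them Ifnlr1, the receptor subunit for interferon lambda, Irf3 (promoter shared with Bcl2l12), and the RNA sensors Ddx58 and Ifih1 (4.29 expected, exact p = 0.686). The inositol phosphate list had 4 of 5 (Ip6k1, Cdipt, Ipmk and Inpp5k, 2.49 expected, exact p = 0.175), the lipid list 5 of 9, with Ppard, Apob and Mttp (5.77 expected), and the innate sensing list 7 of 10, with the chemokine Ccl25, Il22ra1, Rela and Myd88 (6.81 expected). The clock genes Npas2 and Clock were 2 of 5, and the inflammasome sensor Nlrp6 was the 1 antimicrobial gene with peaks in both germ-free libraries. In the antigen presentation list it was H2-K1 and H2-DMa, whose promoter peaks are shared with Brd2 (2 of 4), and among stem cell and Wnt genes Prom1, Tcf7l2 and Rnf43 (3 of 3). Ribosomal and translation genes had 14 of 17, with Rpl7, Eif4a1, Rpl32 (promoter shared with Snora7a) and Eef1b2 (10.6 expected, exact p = 0.108), and mitochondrial respiration genes 12 of 24, with Ndufb8, Atp5c1 (promoter shared with Kin), Ndufs1 and Atp5a1 (16.4 expected, exact p = 0.0545). Eef1b2 and Ndufs1 share 1 promoter and the same peaks. A gene called in both germ-free lists need not have overlapping peaks, and at Nlrp6, Ddx58, H2-K1 and Ccl25 the strongest ones did not overlap. At Ccl25 (chromosome 8, start site at 4349588) they were 4349843 to 4350006 in replicate 1 and 4324603 to 4325149 in replicate 2. The H2-K1 peak of germ-free replicate 1 had 4.04-fold enrichment, the lowest fold of its list.

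Intestinal transcription factors kept their promoter peaks in E. coli libraries more often than other genes of equal rank. Of 16 with peaks in both germ-free libraries, 1 had none in either E. coli library, against 7.79 expected and 66.1% of other genes (exact stratified test, p = 0.000242, adjusted p = 0.0232 over 96 tests). Junction genes had 7 of 24 without a peak, among them Ctnna1, F11r, Cdhr5 and Pkp3 (12.4 expected, exact p = 0.0251, adjusted p = 0.603), and enterocyte genes 4 of 12, namely Krt18, Krt19, Slc51b and Slc7a9 (6.93 expected, exact p = 0.11, adjusted p = 1). By the same exact test the transcription factor call was lost with a promoter window of 2.5 kb (2 of 18, 7.94 expected, adjusted p = 0.174). It was also lost with equal numbers of top peaks and without E. coli replicate 2. Counts stayed below expectation without germ-free replicate 1 (10 of 26, 19.4 expected), germ-free replicate 2 (2 of 17, 9.50 expected) or E. coli replicate 1 (3 of 16, 11.6 expected). Genes are not replicates of the animals, so the test describes these 4 libraries.

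Genes with weaker germ-free peaks lacked an E. coli peak more often, though strong ones did too. From the lowest to the highest quintile of germ-free peak rank, 84.7%, 79.6%, 69.0%, 60.4% and 34.5% of genes had none. Between the germ-free libraries, the share of replicate 2 genes without a peak in replicate 1 fell from 85.2% to 32.8% by rank in replicate 2. That sets 1 library against 1 and not 2 against 2, so the levels are not comparable. Of the 6491 genes marked in germ-free replicate 2, 2226 had a peak in germ-free replicate 1. E. coli replicates 1 and 2 had a peak at 890 and 402 of them. Pairing 1 germ-free with 1 E. coli library gave 63 and 211 genes in both directions together, against 1461 for the real groups, the largest of 3 splits (exact permutation p = 0.333, the smallest possible). Over all regions regardless of genes, 1617 were called in both germ-free and neither E. coli library and 3 the other way. Without germ-free replicate 1 the regions became 14480, and without germ-free replicate 2 they became 2747, while the 3 became 454 without E. coli replicate 2. The 1461 became 5444 without germ-free replicate 1, 561 at a -log10 q of 5 or more and 133 with 500 bp of overlap, and with the 870 most significant intervals of each list there were 73 genes in this direction and 29 in the other.

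**Figure D3:**
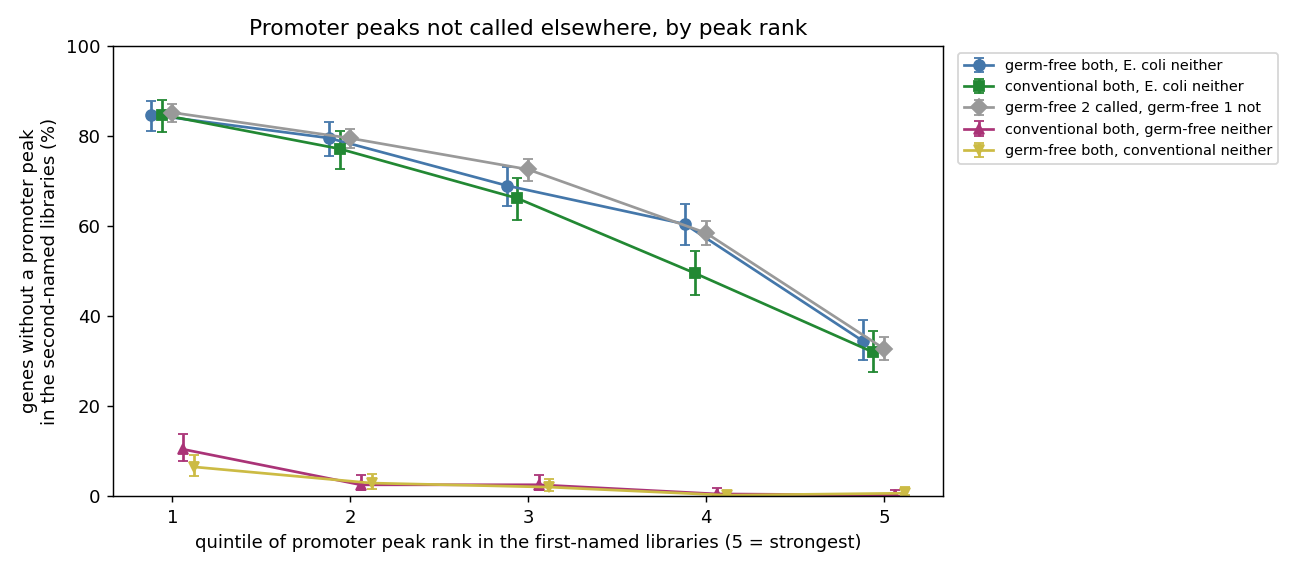
Percentage of genes without a promoter peak in the second-named libraries, by quintile of promoter peak rank in the first-named libraries, with 95% Wilson intervals. The curve between the 2 germ-free libraries (grey) fell from 85.2% to 32.8%, and the germ-free against E. coli curve fell from 84.7% to 34.5%. The grey curve sets library against library and not group against group, so its level is not comparable with the group curves. Between the germ-free and conventional groups, 10.4% or fewer of genes in every quintile had no peak in either library of the other group. Each of these groups holds a long and a short list, which by itself keeps this share small. A further 43.5% of germ-free and 35.7% of conventional genes had a peak in only a single library of the other group.

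Conventional libraries differed from E. coli libraries in the same way, which sets a complete microbiota against a single species. Of 1968 genes with a promoter peak in both conventional libraries, 1218 had none in either E. coli library (61.9%, 95% Wilson interval 59.7 to 64.0), and no gene showed the opposite pattern (17 did without conventional replicate 2). The strongest by rank were Tbx3, a T-box transcription factor, Sepp1, the plasma selenium carrier, Apob, the structural protein of chylomicrons, and Ppard, a lipid-sensing nuclear receptor. Rad21, a cohesin subunit, Shfm1, Hbp1, Tapbpl (in a shared promoter), Zcchc11 and the survival factor Bcl2l1 followed. At Apob (chromosome 12, start site at 7977677) the peaks had 9.91-fold and 14.5-fold enrichment in the conventional and 5.19-fold and 14.6-fold in the germ-free lists.

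By list, 7 of 9 antigen presentation genes lacked an E. coli peak (6.56 expected at equal rank), among them H2-DMa (promoter shared with Brd2), Psmb10, H2-Ab1 and Tap2. Innate sensing genes had 8 of 11 (6.07 expected), with the NF-kB inhibitor Nfkbia, Tnfrsf1a, Il22ra1 and Tollip, and lipid genes 7 of 12 (6.42 expected), with Abcg5 and Apoa1 beside Apob and Ppard. The goblet cell genes Guca2a and Fcgbp were 2 of 3, the enterocyte keratins Krt19 and Krt20 were among 5 of 15, and Crebbp, an acetyltransferase, was 1 of 4. Junction genes had 6 of 22 (11.6 expected, exact p = 0.0117, adjusted p = 0.376), with Tjp3, Cdhr5, Dsc2 and Marveld2, and intestinal transcription factors 3 of 18, namely Esrra, Nr5a2 and Nr1h3 (6.91 expected, exact p = 0.0733, adjusted p = 1). No list passed the exact stratified test in this comparison, and 1 had an unadjusted p under 0.05. By the same exact test junction genes passed without E. coli replicate 1 (10 of 22, adjusted p = 0.0227), and without conventional replicate 1 junction genes (12 of 30) and transcription factors (13 of 29) did (adjusted p = 0.0445 each). Without rank strata the adjusted p was 0.0322 and 0.00507 by Fisher's exact test. The real groups gave the largest count of 3 splits (1218 against 43 and 255, exact permutation p = 0.333). The 1218 became 6128 without conventional replicate 1 and 629 at a -log10 q of 5 or more, and with equal numbers of top peaks 114 genes went this way and 19 the other.

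Conventional and germ-free libraries were compared to ask what the normal microbiota changes. Each group holds 1 long and 1 short list, which by itself keeps counts of both against neither small. Of the 1968 genes marked in both conventional libraries 64 had no germ-free peak (3.25%, 95% Wilson interval 2.55 to 4.13), and of the 2226 marked in both germ-free libraries 55 had no conventional peak (2.47%, 1.90 to 3.20). The 64 were led by Espn, an actin-bundling protein of microvilli (chromosome 4, start site at 152128925), with peaks of 8.49-fold and 11.6-fold in the conventional lists. Next came Ttyh3, a chloride channel, Cebpd, an inflammation-responsive transcription factor, Ncln, Slc7a7, a basolateral amino acid transporter, Mta1, a subunit of a deacetylase complex, Adck5, Chp2, Gm8909 and Hkdc1, a hexokinase. Ncln also had a peak in E. coli replicate 1 and Chp2 in E. coli replicate 2. Sis (the brush border sucrase-isomaltase), Fcgbp and Lrig1 were further members of the fixed lists.

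Antigen presentation genes supplied 3 of the 64. Of 9 with a peak in both conventional libraries, H2-Ab1, which encodes an MHC class II chain, Psmb9, an immunoproteasome subunit, and Tap1, a peptide transporter sharing its promoter with Psmb9, had none in either germ-free library, against 0.445 expected at equal rank. The exact stratified test gave p = 0.00643 and an adjusted p of 0.309, which did not pass; without rank strata the adjusted p was 0.046, and without conventional replicate 1 it was 0.0445 (7 of 18). With the promoter of Psmb9 and Tap1 counted once, 2 of 8 loci were missing (0.351 expected, exact p = 0.0421, adjusted p = 1). The interval there was 34187091 to 34187251 in conventional replicate 1, at 4.95-fold enrichment. Conventional replicate 2 had 34186582 to 34186728 and 34187945 to 34188149, each at 3.62-fold, the lowest fold of that list. Neither overlapped the interval of conventional replicate 1. The lowest folds in the germ-free lists were 4.04 and 3.80, but each fold is relative to its own list. The peak at H2-Ab1 (chromosome 17, 34263594 to 34263739 in conventional replicate 1 and 34263545 to 34264159 in conventional replicate 2) lay downstream of the start site at 34263227. Across the list, 4 and 11 of 20 genes had a promoter peak in the germ-free, 3 and 1 in the E. coli and 9 and 18 in the conventional libraries. Of the 37 lymphocyte and myeloid genes, 0 and 1 had a peak in the conventional libraries.

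**Figure D4:**
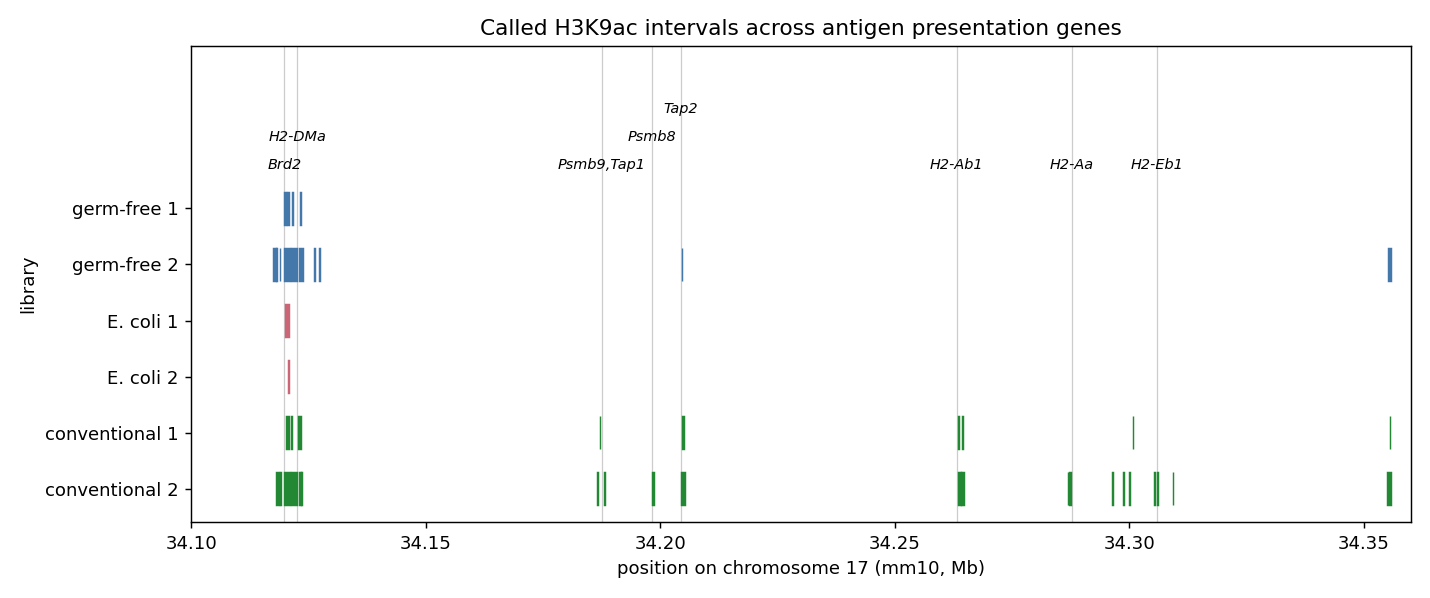
Called H3K9ac intervals (bars, to scale) around the MHC class II genes of chromosome 17 in each library, with start sites of antigen presentation genes and Brd2 as grey lines. The conventional lists hold 9 and 21 intervals here, the germ-free lists 4 and 10 and each E. coli list 1, and H2-Ab1 has intervals in the conventional lists alone.

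The 55 genes of the opposite direction were led by the kinase genes Cdkl2 and Nek8, followed by Aasdh, Aaed1, Mllt1 (an acetyl-lysine reader of the elongation machinery), Ppwd1 (promoter shared with Cenpk), Zfp213, Agmo, the caspase Casp2 and Edc4, a decapping scaffold. None of these 10 had a peak in an E. coli library. Of 24 mitochondrial respiration genes 2 had this pattern, among them Fh1 of the citric acid cycle (0.683 expected at equal rank, exact p = 0.146). No other fixed list had a member among the 55. Exchanging libraries between the groups gave 2807 and 117 genes in both directions together, against 119 for the real groups, so the real groups were not the largest of 3 splits (exact permutation p = 0.667). The counts depended on single libraries: without conventional replicate 1 the 64 became 1410, without germ-free replicate 2 they became 740, and the 55 became 1022 without conventional replicate 2, 825 without germ-free replicate 1 and 106 without germ-free replicate 2. With the longest list of each group alone they were 1541 and 839. By regions, 146 were called in both conventional and neither germ-free library and 183 the other way, which became 6383 without conventional replicate 1 and 8352 without germ-free replicate 1.

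Colonization of either kind was compared with the germ-free state over all 6 libraries. No gene had a promoter peak in all 4 colonized libraries and neither germ-free library, and 11 did without germ-free replicate 2. List length limits this count. Only 248 genes had a peak in both E. coli libraries, and 6673 of 8097 had one in a germ-free library. The count therefore cannot show whether colonization adds the mark. A peak in both germ-free and no colonized library was called for 53 genes. They included the leading genes Cdkl2, Nek8, Aasdh and Mllt1 and the cycle enzyme gene Fh1. Of the 15 ways to choose 2 of the 6 libraries, 4 gave 53 or more such genes (exact permutation p = 0.267, one-sided, smallest possible 0.0667), and the highest of the others was 2653, for germ-free replicate 2 with conventional replicate 2. The 53 became 815 without germ-free replicate 1, 104 without germ-free replicate 2 and 874 without conventional replicate 2. With equal numbers of top peaks in each list, the 53 became 21, and 12 genes had a peak in all 4 colonized libraries alone.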

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

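The test on peak rank was written before its result was seen, and the other tests of this part were chosen after the result was seen. Mitochondrial bases inside called intervals, which no comparison of genes used, came to 11896 and 11924 bp in the germ-free, 11889 and 11847 bp in the E. coli and 12326 and 12295 bp in the conventional libraries, above the 0 that a nuclear histone mark would give.

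The E. coli lists were the shortest, with 1461 promoters called in both germ-free and neither E. coli library. The tables argued against lower sequencing depth, since 3 libraries of other groups had a lower background pileup than E. coli replicate 1 and more peaks. Greater loss at particular gene groups cannot be told apart from loss by rank alone: by the exact stratified test 0 lists lost more peaks than genes of equal rank, at an adjusted or an unadjusted p under 0.05, and 1, the intestinal transcription factors, lost fewer (adjusted p = 0.0232), but only 5 of 18 lists could have passed with all their called genes lost. A lower yield over the whole library, with the weakest peaks lost first, stayed open. Losses fell by 50.2 percentage points from the lowest to the highest quintile of germ-free peak rank. Losses between the germ-free replicates, 1 library against 1, also fell with rank. A lower H3K9ac level over the whole genome after monoassociation, the biological explanation that the design names, makes the same prediction and stayed open as untested.

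Replicate 2 had by far the longer list in the germ-free and the conventional group. A looser q threshold was argued against, since at a -log10 q of 5 or more the longer list still held 3.57 times or more as many intervals in each group. Other calling options were not tested. The list of germ-free replicate 2 alone held no pileup and no repeated intervals (17094 lines for 17094 intervals), so its calling may have differed. Deeper sequencing was argued against as well, since the longer list had the lower background pileup in both groups (ratios 0.790 and 0.922, the first with a background inferred from fold values). Differences in immunoprecipitation between preparations, or between animals, were not tested and stayed open.

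Of 20 antigen presentation genes, 9 and 18 had a promoter peak in the conventional, 4 and 11 in the germ-free and 3 and 1 in the E. coli libraries, so conventional replicate 1 lay below germ-free replicate 2. Immune cells as a large part of the epithelial preparation were argued against, since at most 1 of 37 lymphocyte and myeloid genes had a promoter peak in a conventional library. A smaller part could not be excluded. The conventional lists start at folds of 4.25 and 3.62, and the limit was set after the values were seen. Weak peaks missed in germ-free libraries of other list length cannot be told apart from a difference between groups, since the test at equal rank gave an adjusted p of 0.309 over 9 called genes, of which Psmb9 and Tap1 share 1 promoter. Induction of these genes in the epithelium by the microbiota, a biological explanation, stayed open as untested.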

How the results depend on the processing

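The settings of a fold of 5 or more, the longest lists alone, the regions common to all lists, the shared promoters counted once and the pairwise promoter shares were chosen after the results were seen; all others were planned. With 1 library left in a group, that library's calls stood for the group, and the cause of the changes below was not tested except that fewer libraries ask for less agreement.

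Genes called in both germ-free and neither E. coli library (1461) became 561 at a -log10 q of 5 or more, 73 with equal numbers of top peaks and 133 with 500 bp of overlap (single libraries left out, 1561 to 5444); regions (1617) became 581, 73, 418 with 0.5 or more of the region covered and 1738 to 14480. The opposite genes (0) became 29 with top peaks, 1 at a fold of 5 or more and 3 to 22. The opposite regions (3) became 1 at a -log10 q of 5 or more, 46 with top peaks and 23 to 454. Genes called in both conventional and neither E. coli library (1218) became 629, 114, 165 and 1239 to 6128, and regions (1398) 659, 109, 353 and 1521 to 12693, in the same order of settings. The opposite genes (0) became 19 with top peaks and 0 to 17. The opposite regions (19) became 10 at a -log10 q of 5 or more, 63 with top peaks and 26 to 500.

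Genes called in both germ-free and neither conventional library (55) became 35 with top peaks, 9 with 500 bp, 839 for the longest lists and 57 to 1022 with single libraries left out, and regions (183) 82 at the stricter q, 41 with top peaks and 202 to 8352. Genes of the opposite direction (64) became 23 with 500 bp, 1541 for the longest lists and 71 to 1410. Regions of that direction (146) became 97 at the stricter q, 79 with top peaks, 90 at a fold of 5 or more and 205 to 6383. Genes of both germ-free and none of the colonized libraries (53) became 21 with top peaks, 9 with 500 bp and 53 to 874, and those of all 4 colonized libraries alone (0) 12, 1 at a fold of 5 or more and 0 to 11. The gene lists that passed (1) became 5 without rank strata, 0 with the 2.5 kb window, 0 with top peaks, 0 for the longest lists, 1 with shared promoters counted once and 0 to 4 with single libraries left out.

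The log2 peak number of conventional minus germ-free libraries reversed to 0.64 without germ-free replicate 2 and 0.82 without conventional replicate 1 (range -1.48 to 0.82). E. coli minus germ-free kept its sign (-3.70 to -1.75), as did conventional minus E. coli (1.24 to 3.55). The pairwise promoter shares kept their sign in all settings but 1 (with single libraries left out -10.0 to -3.86 for E. coli minus germ-free, 5.99 to 14.2 for conventional minus germ-free and 12.9 to 21.1 percentage points for conventional minus E. coli). At the stricter q these shares were -30.8, 9.10 and 39.9, with top peaks -16.8, 6.45 and 23.3, and at a fold of 5 or more -12.9, 10.2 and 23.1; the first 2 were -6.94 and 10.1 with all intervals. Without non-promoter regions called in all 6 libraries they were 0.672 (reversed, because these regions weigh most on the shortest lists), 11.2 and 10.6, and without all regions called in all 6 they were -5.85, 12.2 and 18.1. With a replicate block the log2 differences were -2.73, -0.33 and 2.40, each with an exact permutation p of 0.5, the smallest possible; replicate 1 deviated by -0.97, 0.60 and -1.15 from the means of the germ-free, E. coli and conventional groups, so the numbers did not pair the samples, and the block changed no call. The lists start at folds of 3.62 to 4.28, so a promoter without a call was not shown to lack the mark; whether depth sets these floors was not tested.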

Other observations

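The comparison in this part of 1 library per group, and the tests on it, were chosen after the results were seen. Germ-free replicate 2 and conventional replicate 2, the longest lists, are 1 library each, so a difference between groups cannot be separated from one between libraries, and no list passed 0.05 after adjustment. Of 17 clock genes with a promoter peak in the germ-free library, 11 had one in the conventional library and Cry2, Nfil3, Per1, Per2, Per3 and Tef had none (6 against 1.70 expected at equal rank, exact p = 0.00317, adjusted p = 0.0562 over 39 tests). In the planned comparison with both libraries of each group, 0 of 5 clock genes marked in both germ-free libraries lacked a conventional peak. The 6 genes had no peak in germ-free replicate 1 either. Only 2226 of the 6491 genes marked in germ-free replicate 2 had a peak there, so that shorter list cannot decide whether the pattern holds. Per and Cry proteins are the feedback repressors of the molecular clock, Tef drives its output genes, and Nfil3 is a clock-controlled repressor. By the same exact test the Paneth cell list had 2 of 2 (Cd24a and Pnliprp2, adjusted p = 0.0598).

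In the other direction, enterocyte genes had 10 of 26 conventional peaks without a germ-free one (4.11 expected, exact p = 0.00215, adjusted p = 0.0562). They included Alpi, Cyp3a11, Fabp6, Mgam, Mme, Sis, Slc26a3, Slc5a8 and Treh, which encode brush border enzymes such as intestinal alkaline phosphatase (Alpi) and maltase (Mgam), the ileal bile acid binding protein (Fabp6) and the anion exchanger Slc26a3. In the planned comparison, 1 of 15 enterocyte genes marked in both conventional libraries had no germ-free peak (0.443 expected). For antimicrobial genes this was 0 of 2. The next counts are again of 1 library per group. Genes that share a promoter, such as Psmb9 and Tap1 of the antigen presentation list, were counted separately in them. Of 6 antimicrobial genes, 4 had a conventional peak alone (1.03 expected, exact p = 0.00767, adjusted p = 0.0598): Duox2 and Duoxa2, which form the hydrogen peroxide-producing oxidase of the epithelium, Pigr, which carries IgA into the lumen, and Sprr2a1. Antigen presentation genes had 7 of 18 (2.56 expected, exact p = 0.00432, adjusted p = 0.0562). By the exact stratified test 5 of 39 tests had an unadjusted p under 0.05 and 0 an adjusted one.

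The strongest regions common to all lists lay outside promoters. The region with the highest minimum rank over the 6 libraries (chromosome 2, 98662161 to 98663051, intergenic) had folds of 241 and 131, 253 and 148, and 146 and 146 in the germ-free, E. coli and conventional lists, and another intergenic one, the strongest in conventional replicate 2, followed (chromosome 9, 35305141 to 35305665). Further ones clustered near the start of chromosome 9. Such regions were not compared with an annotation of repeats here and are not read as H3K9ac. Of the nuclear regions called in all 6 libraries, 134 lay outside promoters and 242 at promoters.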
